A study of Homo sapiens with 18 samples.

How the data were processed

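The series holds 18 one-colour Agilent whole-genome expression arrays of EPI-200, a reconstructed human epidermis model grown as a layered tissue from keratinocytes. Per the labels, each tissue was irradiated with alpha-particles along a thin line at 0.5 Gy or was a 0 Gy control. RNA was taken 4 h later from strips lying 250-500, 500-750 and 750-1000 µm from the line, so that the strips hold bystander cells. There were 6 groups (2 doses by 3 distances) of 3 replicates each. The replicates are 3 experiments, as the labels and the replicate numbers give them, and the p-values measure the spread between these samples. The free-text descriptions of the samples name other radiation types, doses and times than their titles and characteristics. The titles and characteristics were followed, since they match each other and the group structure.

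The deposited values are background-subtracted intensity values (the processed signal of each spot, not on a log scale), per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1.3.1, which subtracted a fitted background surface and detrended each array, with no scaling between arrays. The deposited series table holds the same values: the largest difference from the scanner files was 0. Each array has 45015 spots, of which 43376 are not control spots, for 41000 probes. Probes were named from the current human gene table where their accession or symbol was found in it. That table named 28610 probes, 510 kept the name in the files and 11880 had none. X-inactivation and Y-linked genes (76 probes) were left out of every step. Near-identical paralogs such as SAA1 and SAA2, the metallothioneins and the AKR1C genes may share signal on such probes.

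Each array was scaled to its 75th percentile, a floor of 0.02 of that level was set, log2 was taken, spots that the scanner software marked as unusable were left out and the spots of a probe were averaged. A probe was kept when it was well above background, by the scanner software's test, on all arrays of at least 1 group. This kept 22308 probes, of which 17710 had a symbol, for 12612 genes. The number of arrays limits the precision.

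Groups were compared with limma 3.58.1 in R 4.3.3 (reading with data.table, version 1.17.8). The model had 6 group means, with the slide as a random block and moderated variances. P-values were two-sided and adjusted by Benjamini-Hochberg over the probes kept in each comparison, with a threshold of 0.05. The comparisons were 0.5 Gy against 0 Gy at each distance and averaged over the distances, the dose by distance interaction, the near dose effect minus the far one, and the near against the far strips within each dose. A slide carried 3 arrays of 1 dose and 1 experiment, so dose and slide coincide within an experiment. The distance set the array position on the slide, and the experiment set the scan day. Levels after subtracting group means were compared between arrays to see whether equal replicate numbers go together. They correlated from 0.161 to 0.383 for equal numbers at 250-500 µm, against -0.273 to 0.059 for unequal ones, from 0.19 to 0.432 against -0.232 to -0.047 at 500-750 µm, from 0.608 to 0.658 against -0.463 to -0.118 at 750-1000 µm, and for slide means from 0.444 to 0.547 against -0.498 to -0.111. Subtracting group means ties these ranges together: where equal numbers correlate positively, unequal ones must on balance correlate negatively. The numbers were taken to pair the samples, by experiment or by scan day, which coincide. Values with the replicate as a block are given where the call or the count changes.

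A total of 24 gene lists was tested with limma's camera on the moderated statistics, 1 probe per gene, with a preset correlation of 0.01 and again with a correlation estimated from the residuals. The genes named were, per comparison, up to 10 in each direction with the largest change among those past the threshold with the same sign in every pair. For genes named this way, equal sign in every pair was a condition and not added support. Pairs at different distances also share slides. Where fewer passed, up to 5 per direction were filled by the smallest p of the averaged comparison, and given as values. To these were added up to 4 members per list and a panel of 12 genes chosen in advance. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Further list members and single genes named beside these were chosen after their values were seen.

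After the data were seen, arrays with under 30% of probes well above background or a median correlation under 0.9 with the others were called poor. This picked 2 arrays. Fits without them, with the replicate as a second block, cover 16 arrays and 7 dose pairs, and are called the 16-array fit. The naming rule was then also applied to that fit. Values after ± are standard errors from limma with 3 replicates per group, or with the arrays left in the 16-array fit.

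Alternatives planned ahead were quantile normalization, normexp background correction (offset 50), both together, the series table, no filter, a filter on all 18 arrays, no slide block, the slide as a fixed block, slide means, the replicate as a block, an intensity trend with robust variances, only the groups compared, and leaving out each replicate and each array. Alternatives added after seeing the data were a floor of 0.1, array weights, leaving out the poor arrays, and the 16-array fit under other processing. Other splits of the samples were fitted in the same way. Both fits were tested on simulated data in which 100 probes were changed by each amount. With all 18 arrays, 17% of the changes of 1 and 59% of the changes of 2 (log2) were called. The 16-array fit called 87% and 98%, and 31 unchanged probes against 5. Those 31 were a larger share of its calls than the adjusted p threshold allows, so its adjusted p-values may be too small. Its slide correlation was estimated at 0.148 where 0.26 was simulated. With all 18 arrays it was estimated at 0.199 where 0.227 was simulated.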

Results

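Expression was measured in 18 arrays, with 3 replicates of each of 6 groups: 0 Gy and 0.5 Gy tissue, each at 250-500, 500-750 and 750-1000 µm from the irradiated line. On 16 of the arrays the 75th percentile of the signal lay between 110 and 423.4 intensity units, and between 48.7% and 61.7% of probes were well above background. The array of 0.5 Gy tissue at 250-500 µm, replicate 2, was dim, with a 75th percentile of 10.8 and 16.7% of probes above background. The array of 0 Gy tissue at 500-750 µm, replicate 1, was scattered: its median correlation with the others was 0.88, against 0.958 to 0.976 for the arrays not called poor. Both arrays are part of the fit to 18 arrays, and the probe counts of each comparison below are also given without them.

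**Figure D1:**
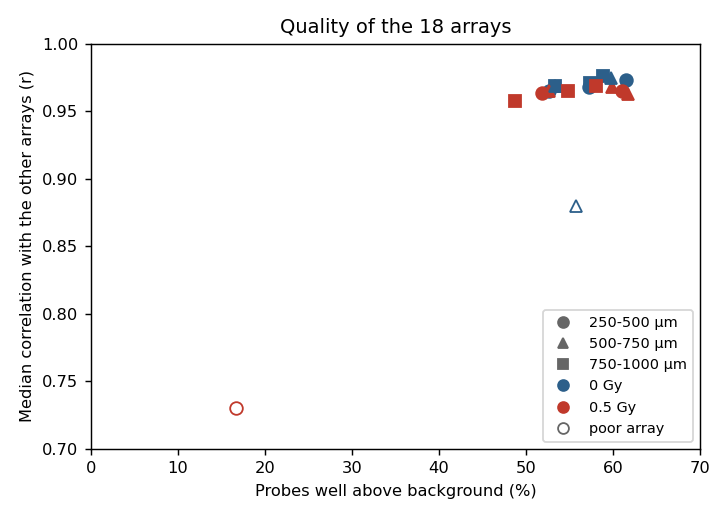
Each point is an array, with the percentage of probes well above background on the x axis and its median correlation with the other arrays on the y axis. The dim array sits at 16.7% and 0.73 and the scattered one at 55.7% and 0.88, while the other 16 lie between 48.7% and 61.7% and at 0.958 or more.

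The first question was what cells that were not hit express 4 h after their neighbours were irradiated, averaged over the 3 distances. CYP1B1, a cytochrome P450 enzyme that oxidises hormones and foreign compounds, rose by 3.77 ± 0.22 log2 units in 0.5 Gy tissue (limma, 18 arrays, adjusted p 8.34e-07, higher in 9 of 9 pairs). DMBT1, a secreted scavenger protein of epithelial defence, rose (adjusted p 0.0081, 9 of 9 pairs). Its 0 Gy level was above background on 1 of 9 arrays, and DMBT1 was at least 3.62-fold higher at 750-1000 µm. With all arrays its bound at 250-500 µm was 10.2-fold, but this includes the dim array and is not a firm minimum. The fit without the poor arrays, with the replicate as a second block, gave 3.22 ± 0.37 log2 units there, below that bound. FST, which encodes the activin inhibitor follistatin, fell (adjusted p 0.0174), at least 1.41-fold lower at 250-500 µm and 3.07-fold at 750-1000 µm, and ZBED2, a transcription factor of keratinocytes, fell by 1.10 ± 0.16 (adjusted p 0.0383), each lower in 9 of 9 pairs. MMP1, the interstitial collagenase, fell by 1.32 ± 0.20 (adjusted p 0.039, lower in 8 of 9 pairs). Equal sign in all pairs was a condition of the naming rule, which MMP1 did not meet for this comparison.

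Those 5 probes, 2 higher and 3 lower, passed the threshold with all arrays. With the replicate as a block 33 passed, 10 higher and 23 lower. With the arrays of a slide averaged (6 samples) 0 passed, with the filter on all 18 arrays 1, and without replicate 1, 2 or 3 the count was 3, 1 and 1. Leaving out the 2 poor arrays without the replicate block gave 14, 7 higher and 7 lower, at a slide correlation of 0.798. The 16-array fit, chosen after seeing the data, combines both steps, at a slide correlation of 0.26. In that fit 1471 passed, 611 higher and 860 lower, for 1085 genes, and the 5 were all among them. With fewer samples, that fit called 3 probes without replicate 3, 1924 without replicate 1 and 154 without replicate 2. With all 18 arrays, leaving out the dim array gave 19 probes, leaving out 0 Gy 500-750 µm replicate 2 gave 7 or 0.5 Gy 250-500 µm replicate 3 gave 6, and leaving out the scattered array gave 6. The count was 2 without 0 Gy replicate 3 at 250-500 or 750-1000 µm or 0.5 Gy replicate 2 at 500-750 or 750-1000 µm, and 3 without any of the other 10 arrays. The dim array also lowered the median log2 change of all probes to -0.133, against -0.038 in the 16-array fit.

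PGLYRP2, an enzyme that cleaves bacterial peptidoglycan, rose by 2.11 ± 0.06 in the 16-array fit (adjusted p 2.41e-07). The serum amyloid genes SAA1 and SAA2 rose by 1.69 ± 0.07 and 1.66 ± 0.08, SERPINA3, a protease inhibitor of the acute phase, by 1.64 ± 0.13, and SOD2, the mitochondrial superoxide dismutase, by 1.55 ± 0.07. Complement factor B (CFB) rose (adjusted p 0.000167) from a 0 Gy level above background on 1 of 9 arrays, and was at least 8.14-fold higher at 500-750 µm. CYP1A1, a relative of CYP1B1, rose by 1.52 ± 0.18, and the antimicrobial S100A7A was at least 3.1-fold higher at 500-750 µm. Each of these 8 genes was higher in 7 of 7 pairs, as the naming rule required. None of the 8 passed with all 18 arrays, with adjusted p from 0.0733 to 0.903.

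In the same fit MMP10 and MMP9, which cleave matrix proteins, fell by 1.72 ± 0.12 and 1.47 ± 0.07, KRT19, a keratin of simple and early epithelial cells, by 1.41 ± 0.09, and PHLDA1, induced by growth factor signalling, by 1.36 ± 0.06, each lower in 7 of 7 pairs, again as that rule required. PTGS2, the inducible cyclooxygenase, fell by 1.04 ± 0.05 (adjusted p 4.88e-06), IL1B by 1.01 ± 0.05 (adjusted p 3.86e-06), and MMP1 and MMP3 by 1.18 ± 0.06 and 1.11 ± 0.12. G0S2, HS3ST1, SLC13A5, RALGPS1 and ANTXR2 were also among the 10 that fell the most, the first 3 and RALGPS1 to levels near the background. CDKN1A, the p53-induced inhibitor of the cell cycle, had a difference of 0.04 ± 0.06 (adjusted p 0.693), and MDM2, which degrades p53, of -0.18 ± 0.09 (adjusted p 0.264). GDF15, a stress cytokine, had -0.32 ± 0.09 (adjusted p 0.0548), and the keratins KRT14 and KRT10 and the barrier protein FLG had 0.09 ± 0.06, 0.04 ± 0.08 and -0.12 ± 0.10. The probes of IL6 and CXCL8 did not pass the filter.

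**Figure D2:**
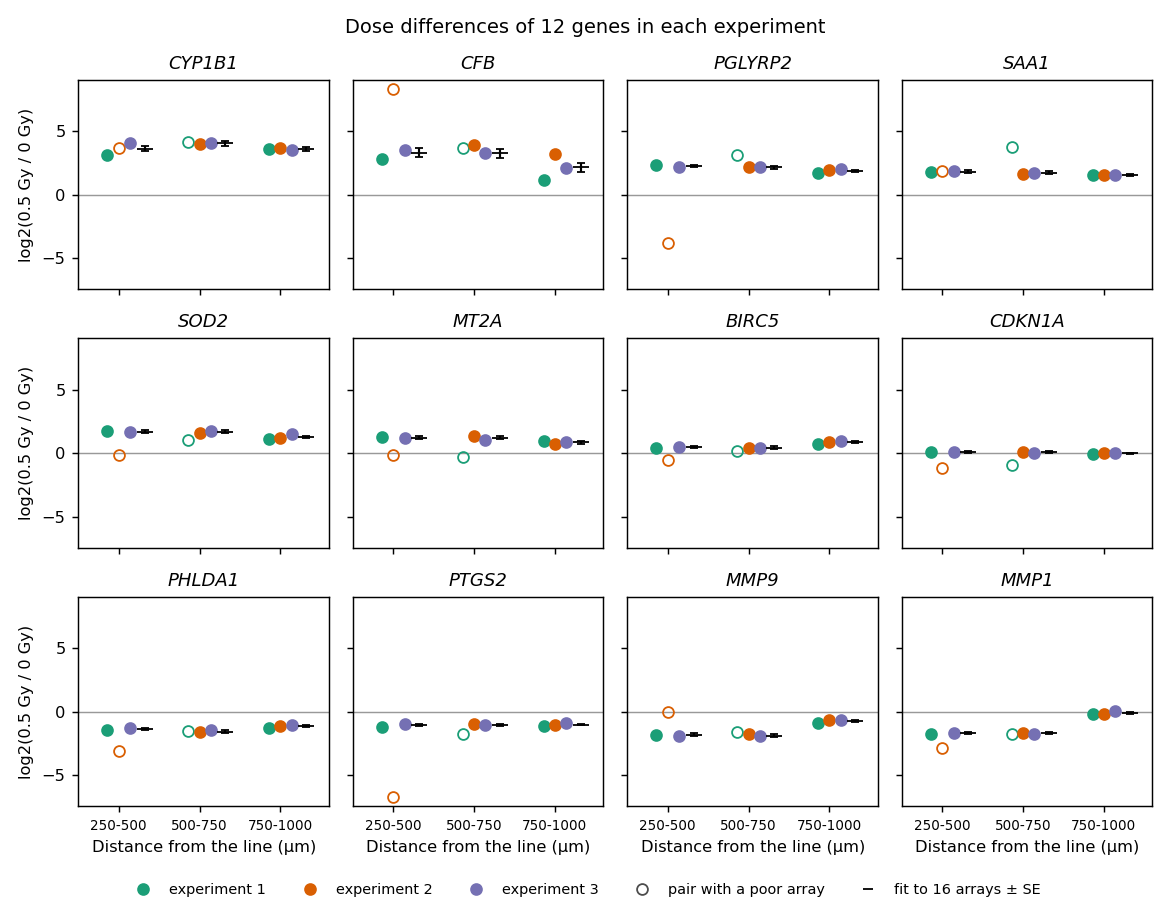
Each panel plots, for one gene, the log2 difference between 0.5 Gy and 0 Gy tissue (y axis) at each distance in µm (x axis). Points are experiments, open where the pair has a poor array, and the bars are the 16-array fit with its standard error: CYP1B1 lies between 3.59 and 4.04 at each distance, and MMP1 is at -1.71, -1.71 and -0.11.

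Among the gene lists, 8 of 24 passed camera's test for the averaged dose with all 18 arrays, and 3 of these, the immediate early, matrix and metallothionein lists, also with an estimated correlation. Of 26 immediate early and stress genes, 0 passed alone with all arrays (0 higher and 5 lower adjusted over the list alone) and the list fell, with a median of -0.36 (adjusted p 1.11e-10, and adjusted p = 0.00109 with an estimated correlation). Without the poor arrays, in the 16-array fit, 14 of the 26 fell and 0 rose (1 higher and 19 lower adjusted over the list alone), with a median of -0.37 and adjusted p 3.07e-23. Among them the transcription factors FOS, MYC and EGR1 fell by 0.96, 0.77 and 0.68, the phosphatase DUSP6 by 0.88 and the growth factor AREG by 0.66. In the matrix and proteolysis list 1 of 18 members fell with all arrays, MMP1 (0 higher and 4 lower adjusted over the list alone), and the list fell (median -0.25, adjusted p 0.0031, and adjusted p = 0.027 with an estimated correlation). The 16-array fit had 7 lower, among them INHBA (-1.22), an activin subunit, and the urokinase PLAU (-0.81), and 1 higher, TGFBI (0.37), or 3 higher and 8 lower adjusted over the list alone (adjusted p 1.59e-12).

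Metallothioneins, small proteins that bind zinc and copper, rose as a list with all arrays (9 measured, median 0.53, adjusted p 1.11e-10, and adjusted p = 0.0071 with an estimated correlation; 0 passed alone and 2 higher adjusted over the list alone). The 16-array fit called 6 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone, led by MT2A (1.10) and MT1G (0.70). Genes of G2 and mitosis rose as a list with a median of 0.26 over 20 members (18 arrays, adjusted p 2.73e-06, but adjusted p = 0.115 with an estimated correlation; 0 passed, on the list alone too). The 16-array fit called 12 of the 20 higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 0.40 and adjusted p 5.22e-15. They include survivin (BIRC5, 0.59), the kinesin KIF2C (0.52) and the mitotic kinases AURKA (0.69) and PLK1 (0.60). DNA replication genes rose with a median of 0.05 over 26 members with all arrays (adjusted p 0.0189, but adjusted p = 0.555 with an estimated correlation; 0 passed, on the list alone too), and in the 16-array fit 8 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.28, adjusted p 6.06e-10). Among these 8 were the nuclease FEN1 (1.08), the licensing factor CDT1 (0.57) and MCM3 (0.33), a helicase subunit.

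Basal keratinocyte genes fell as a list (18 members, median -0.33, adjusted p 0.000851 with all arrays, but adjusted p = 0.387 with an estimated correlation; 0 passed, 0 higher and 3 lower adjusted over the list alone). Of the 18 members, 6 fell and 1 rose in the 16-array fit, or 2 higher and 11 lower adjusted over the list alone (adjusted p 0.000291). LAMA3 and LAMB3, which help to anchor the epidermis, fell by 0.70 and 0.42 and the collagen receptor ITGA2 fell too, while the basal keratin KRT5 rose by 0.42. Cholesterol synthesis genes fell (24 members, median -0.29, adjusted p 0.00308, but adjusted p = 0.387 with an estimated correlation; 0 passed, on the list alone too). The 16-array fit had 0 higher and 5 lower (13 lower adjusted over the list alone), among them HMGCS1, an early enzyme of the pathway, at -0.36, with adjusted p 0.000819 and adjusted p = 0.166 with an estimated correlation. Interferon-stimulated genes fell (17 members, median -0.16, adjusted p 0.0166, but adjusted p = 0.0756 with an estimated correlation; 0 passed, 2 lower adjusted over the list alone). MX1, IFI27, SAMD9 and OASL fell by 0.98, 0.96, 0.48 and 0.26 and OAS1 rose by 0.67 in the 16-array fit (1 higher and 5 lower adjusted over the list alone, adjusted p 0.0373, and adjusted p = 0.125 with an estimated correlation).

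The other 16 lists did not pass with all arrays, with adjusted p from 0.056 to 0.945. Of these, 4 passed in the 16-array fit. NRF2 targets, which counter oxidative stress, rose (5 of 21 higher and 0 lower, 7 and 0 adjusted over the list alone, adjusted p 2.45e-05), with the aldo-keto reductases AKR1C1 and AKR1C3 at 0.72 and 0.62. Double-strand break repair genes rose (2 of 23, 2 adjusted over the list alone, adjusted p 0.0156), namely FANCA (0.68) and RAD54L (0.47). Activated keratinocyte and antimicrobial genes rose (3 of 19, 3 adjusted over the list alone, adjusted p 0.0312, but adjusted p = 0.409 with an estimated correlation), namely S100A7A, CAMP (0.74) and DEFB4A (0.67), which are antimicrobial. TGF-beta and Wnt feedback genes fell (2 of 16, 2 adjusted over the list alone, adjusted p 0.0373), namely ID1 (-0.72) and DKK1 (-0.46), inhibitors of differentiation and of Wnt signalling. Before the poor arrays were left out, 0 members of these 4 lists passed, and adjusted over the list alone 1 activated keratinocyte gene was higher and 1 TGF-beta and Wnt gene lower.

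The p53 targets had 2 higher, SESN1 (0.47) and BTG2 (0.33), and 1 lower, PLK2 (-0.34), of 29 in the 16-array fit (2 and 3 adjusted over the list alone, adjusted p 0.6, 0.387 with all arrays). NF-kB targets and inflammatory cytokines had SOD2 and TNFAIP2 (0.66) higher and PTGS2, IL1B, IL1A (-0.67) and IER3 (-0.46) lower of 19 (3 and 5 adjusted over the list alone, adjusted p 0.195, 0.945 with all arrays). In the hypoxia list 3 of 21 fell, led by ANGPTL4 (-0.86), a lipase inhibitor (6 adjusted over the list alone, adjusted p 0.0736), and in the unfolded protein list 3 of 25, led by the enzyme MTHFD2 at -0.40 (3 adjusted over the list alone, adjusted p 0.127). Of 28 granular and cornified layer genes CASP14 and CST6 fell, by 0.34 and 0.33 (1 higher and 3 lower adjusted over the list alone, adjusted p 0.523), and of 16 heat shock genes HSP90AB1 rose by 0.33 (1 adjusted over the list alone, adjusted p 0.29). Spinous keratinocyte genes (16 measured, adjusted p 0.898) and oxidative phosphorylation genes (31, adjusted p 0.501) had 0 past the threshold in limma, on the list alone too. So did the markers of other cell types, namely melanocytes (6 measured, adjusted p 0.653), dermal fibroblasts (6, adjusted p 0.6), endothelium (4, adjusted p 0.764) and immune cells (5, adjusted p 0.792). With all arrays 0 members of these 12 lists passed, and adjusted over the list alone 2 NF-kB targets were higher and 1 lower. Unadjusted p under 0.05 was reached by 601 of all probes with 18 arrays and by 5180 in the 16-array fit.

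**Figure D3:**
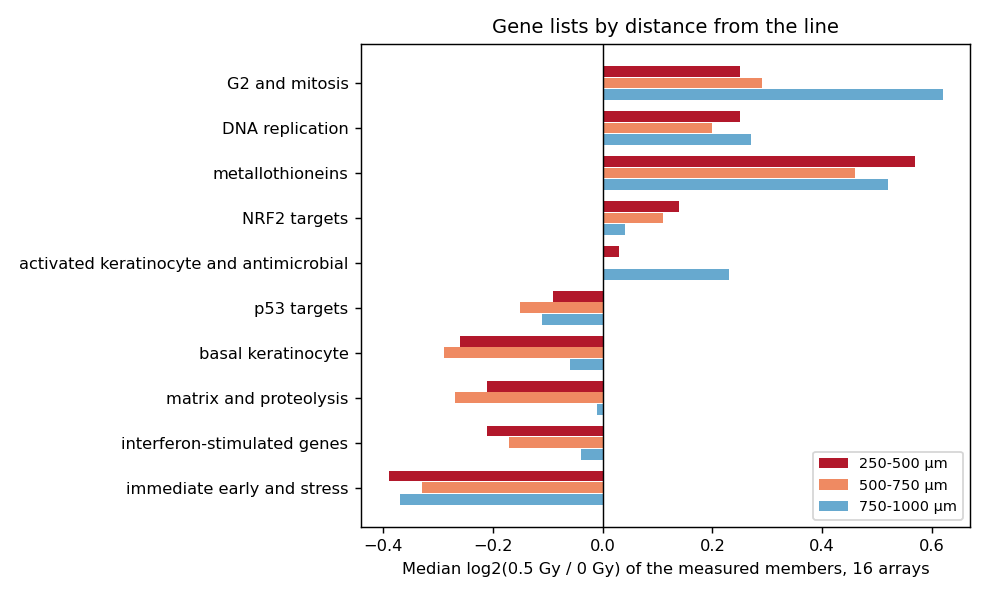
Bars give, for 10 gene lists, the median log2 difference between 0.5 Gy and 0 Gy tissue of the measured members (x axis) at each of the 3 distances, in the 16-array fit. G2 and mitosis genes have medians of 0.25, 0.29 and 0.62 from near to far, and immediate early genes of -0.39, -0.33 and -0.37.

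The next question was how the strip nearest to the line, 250-500 µm away, differed from its control. CYP1B1 rose by 3.63 ± 0.31 with all arrays (adjusted p 0.000199), and DMBT1 was higher (adjusted p 0.0197). The bound of 10.2-fold for DMBT1 includes the dim array, and the 16-array fit gave 3.22 ± 0.37 log2 units, below that bound. MMP1 fell by 2.10 ± 0.28 (adjusted p 0.02). BMP6, a bone morphogenetic protein, and CDH4, a cadherin, fell to levels not above background on any array of the group, by at least 1.34-fold (adjusted p 0.031) and at least 1.13-fold lower (adjusted p 0.032), but with normexp the log2 difference of CDH4 was 0.09. Without the 2 poor arrays but with no replicate block 24 probes passed. A total of 328 probes passed in the 16-array fit, 161 higher and 167 lower. CEACAM6, a cell adhesion glycoprotein, fell by 1.63, MAL, a raft protein of differentiated epithelia, by 1.51 and MX1, an interferon-induced antiviral GTPase, by 1.75. PSTPIP2, an adaptor of the actin cytoskeleton, rose by 1.49.

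The fit to all 18 arrays called 5 probes, 2 higher and 3 lower, and 6 with the replicate as a block. It was 3 with quantile normalization, 2 with normexp, 1 with the filter on all 18 arrays, 0 with only the groups compared and 1, 0 and 0 without replicate 1, 2 or 3. The count was 12 without the dim array, 1 without 0 Gy 250-500 µm replicate 1 or replicate 3, 2 without replicate 2 of that group and 3 without 0.5 Gy 250-500 µm replicate 3. It ranged from 5 to 39 in the 16-array fit when a replicate was also left out. The median log2 change of all probes was -0.352 with all arrays, -0.278 after quantile normalization and 0.003 after normexp, so small changes there are relative to that shift. By lists, basal keratinocyte genes fell (median -0.85, adjusted p 0.000149, but adjusted p = 0.378 with an estimated correlation), as did immediate early genes (-0.71, adjusted p 0.000495 and 0.187) and matrix genes (-1.02, adjusted p 0.0332 and 0.187). Metallothioneins rose (0.16, adjusted p 0.00458, and adjusted p = 0.378 with an estimated correlation). Without the poor arrays 9 lists passed, and 8 of them also with an estimated correlation. Lower were basal keratinocyte (median -0.26, adjusted p = 0.00115 with an estimated correlation), immediate early (-0.39, 1.74e-16), interferon-stimulated (-0.21, 0.0427) and matrix genes (-0.21, 4.09e-16). Higher were DNA replication (0.25, 0.00255), G2 and mitosis (0.25, 0.000363), metallothionein (0.57, 0.0333) and NRF2 genes (0.14, 0.00777). Cholesterol synthesis genes fell (-0.15, adjusted p 0.0122, but adjusted p = 0.286 with an estimated correlation).

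In the middle strip, 500-750 µm from the line, CYP1B1 rose by 4.09 ± 0.31 with all arrays (adjusted p 3.97e-05), and it was the 1 probe past the threshold. Without the poor arrays 24 probes passed with no replicate block, and 278 in the 16-array fit, 132 higher and 146 lower. SERPINA3 rose there by 2.07, PGLYRP2 by 2.14 and the synapse protein gene LRRTM1 was at least 3.15-fold higher. MMP10, CEACAM6 and MMP9 fell by 2.29, 1.88 and 1.88, and INHBA by 1.67. Immediate early, interferon-stimulated and matrix genes fell as lists with all arrays (adjusted p = 0.0313, 0.0377 and 0.0231 with an estimated correlation), and metallothioneins rose (adjusted p = 0.0231 with an estimated correlation).

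Calls at this distance also depended on the fit, with 0 for only the groups compared, for the filter on all 18 arrays, for normexp with quantile normalization and whichever replicate was left out. With the replicate as a block 2 probes passed, and without 0.5 Gy 500-750 µm replicate 2 also 2. The 16-array fit gave 168 without replicate 1, 1 without replicate 2 and 0 without replicate 3. Cholesterol synthesis, G2 and mitosis, basal keratinocyte and endothelial lists passed with all arrays at adjusted p 0.0121, 0.00798, 0.047 and 0.0332, but at adjusted p = 0.544, 0.466, 0.766 and 0.229 with an estimated correlation. The endothelial list has 4 measured members, a median of 1.14 there, and did not pass in the 16-array fit. That fit had 12 lists past the threshold. Basal keratinocyte (median -0.29), immediate early (-0.33) and matrix genes (-0.27) fell, and double-strand break repair (0.12), DNA replication (0.20), G2 and mitosis (0.29), metallothionein (0.46) and NRF2 genes (0.11) rose, and these 8 also passed with an estimated correlation, at adjusted p = 0.0339 or less. Cholesterol synthesis, dermal fibroblast, granular layer and interferon-stimulated genes fell at adjusted p 0.0185, 0.039, 0.0326 and 0.032, but at adjusted p = 0.282, 0.282, 0.247 and 0.093 with an estimated correlation.

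The strip farthest from the line, 750-1000 µm away, holds no poor array. Its 0.5 Gy arrays were nevertheless dimmer than its 0 Gy arrays in every experiment. The 75th percentile of the signal was 110 against 187.6, 222.8 against 294.6 and 309.3 against 341 in experiments 1, 2 and 3. Whether this signal level bears on the calls was not tested. CYP1B1 rose by 3.59 in both fits (18 arrays, adjusted p 0.00023; 16 arrays, ± 0.18, adjusted p 2.57e-05), and it was the 1 probe past the threshold with all arrays, and with the replicate as a block. Without the 2 poor arrays but with no replicate block 3 probes passed. The 16-array fit called 787 probes, 314 higher and 473 lower, and DLGAP5, which builds the mitotic spindle, rose by 1.14. The balance of directions depended on the processing: with normexp in that fit 2766 were higher and 2212 lower. With its filter on all 16 arrays 582 were higher and 586 lower. FST, SLC13A5, which imports citrate, and the growth factor BMP2 fell there to background, by at least 3.07-fold, 1.86-fold and 1.86-fold. MMP3 fell by 1.24, FOS by 1.05, and IL17RD, which dampens growth factor signalling, by 1.15, while the viral RNA sensor TLR3 fell by 1.11.

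As lists with all arrays, G2 and mitosis genes rose the most at this distance (median 0.62, adjusted p 3.81e-31, and adjusted p = 3.31e-06 with an estimated correlation). Immediate early genes fell (adjusted p 2.3e-15) and metallothioneins (adjusted p 9.1e-13) and activated keratinocyte genes (median 0.23, adjusted p 2.33e-08) rose, and these calls held with an estimated correlation at adjusted p = 1.03e-05, 0.0016 and 0.0211. DNA replication genes rose and cholesterol synthesis genes fell at adjusted p 6.55e-08 and 0.0163, but at adjusted p = 0.115 and 0.69 with an estimated correlation. Of these 6 lists, all passed in the 16-array fit, and all but cholesterol synthesis also with an estimated correlation (adjusted p = 0.0427 or less, and adjusted p = 0.213 for cholesterol synthesis). NRF2 targets rose there too (median 0.04, adjusted p 0.0456, but adjusted p = 0.213 with an estimated correlation). The 1 probe past the threshold with all arrays became 0 with the filter on all 18 arrays, with normexp and quantile normalization together and whichever replicate was left out. The 787 probes of the 16-array fit became 23, 2 and 0 when replicate 1, 2 or 3 was left out.

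A further comparison asked whether distance changed the dose effect. With all 18 arrays limma called 0 probes for the interaction and 0 for the near minus far difference (168 and 278 at an unadjusted p under 0.05; 0 and 0 with the replicate as a block, 329 and 384 at an unadjusted p under 0.05). The 16-array fit called 25 and 21, and of the 21, 18 were lower near the line and 3 higher. Of these, 16 are the probes that represent a gene, and the other 5 are 3 without a symbol, a second probe of IFI27 and hCG_1984468. MMP1 fell by 1.71 at 250-500 and at 500-750 µm and had -0.11 at 750-1000 µm, a difference of -1.59 ± 0.10 (adjusted p 0.000318). IFI27, an interferon-induced membrane protein, differed by -1.21 ± 0.10 (adjusted p 0.00265), ANXA1, a regulator of inflammation, by -0.98 ± 0.10 (adjusted p 0.0125), KRT19 by -1.17 ± 0.15 and MMP9 by -1.10 ± 0.12. CYP1B1, SAA1 and PTGS2 were not among them. As lists with all arrays, activated and basal keratinocyte, G2 and mitosis and matrix genes had lower dose effects near the line and melanocyte genes higher, at adjusted p from 8.04e-07 to 0.0342, but none held with an estimated correlation (adjusted p = 0.192 to 0.351). Without the poor arrays the basal keratinocyte, G2 and mitosis and matrix lists held, at adjusted p = 0.00161, 4.14e-05 and 8.95e-12 with an estimated correlation, while activated keratinocyte and dermal fibroblast genes had adjusted p 5.98e-06 and 0.000685, but adjusted p = 0.0814 for both with an estimated correlation.

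The counts of the interaction and of the near minus far difference were each 1 without the dim array or without 0.5 Gy 250-500 µm replicate 1. The 16-array fit gave from 1 to 3 and from 0 to 4 when a replicate was left out. In that fit 90 probes were higher and 115 lower at both 250-500 and 500-750 µm, strips that share their slides. A total of 46 were higher and 70 lower at all 3 distances. Across probes, which are not independent replicates, the dose effects correlated with Pearson's r of 0.168 between 250-500 and 500-750 µm, 0.303 between 250-500 and 750-1000 µm and 0.145 between 500-750 and 750-1000 µm (Spearman's rho 0.169, 0.324 and 0.187). The 16-array fit gave r of 0.564, 0.235 and 0.193. Other splits of the slides that part all pairs gave r of at most 0.199, 0.311 and 0.138 with all arrays and 0.43, 0.401 and 0.299 in the 16-array fit, with 4 splits each, too few for a share under 0.05.

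Finally, near and far strips of the same tissues were compared, to see whether place alone mattered. In 0 Gy tissue limma called 0 probes with all arrays (8 at an unadjusted p under 0.05), 0 with the replicate as a block (8) and 0 in the 16-array fit (404), and 0 of 24 lists passed. CYP1B1, SAA1 and MMP1 are among the genes with no call there, and MMP1 had -0.02 in the 16-array fit. Arrays of a 0 Gy slide lay within the spread of repeated spots, so the same RNA on each is not excluded. The 0 calls therefore do not settle whether place mattered. In 0.5 Gy tissue 3 probes passed with all arrays, all lower near the line. MMP1 had a difference of -2.0 ± 0.25 (adjusted p 0.011), MX1 of -2.71 ± 0.37 (adjusted p 0.023), and BMP6 was at least 1.43-fold lower (adjusted p 0.011). The 16-array fit called 619 in 0.5 Gy tissue, 203 higher and 416 lower near the line. The same arrays without the replicate block gave 397, 210 higher and 187 lower.

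Among the 416 were the proteases MMP10 (-1.36) and MMP9 (-1.10), CEACAM6 (-1.42), LAMA3 (-0.94), the antimicrobial S100A9 (-0.83) and S100A7 (-0.95), and IFITM1, which blocks virus entry (-1.58). The cell death activator HRK (-1.66) and MARCKSL1 (-1.45), an actin regulator, were also lower near the line. Higher near the line were VPS50 (2.03), of endosome recycling, PDP1 (1.69), an activator of pyruvate dehydrogenase, ACP6 (1.13), a phosphatase of lysophosphatidic acid, and the melanocyte antigen MLANA (1.09). With all arrays, the lists of matrix (median -0.75), G2 and mitosis (-1.0), basal keratinocyte (-0.78) and activated keratinocyte genes (-0.97) were lower near the line and melanocyte genes higher (0.37), at adjusted p from 3.71e-07 to 0.0276, but none held with an estimated correlation (adjusted p = 0.147 to 0.317). The first 3 were lower in the 16-array fit (median -0.36, -0.36 and -0.21) and held with an estimated correlation, at adjusted p = 3.94e-14, 2.02e-06 and 0.000399. Activated keratinocyte, dermal fibroblast and interferon-stimulated genes were lower at adjusted p 2.11e-06, 0.00188 and 0.02, but at adjusted p = 0.075, 0.105 and 0.0858 with an estimated correlation.

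The count of 3 for 0.5 Gy tissue was 0 with normexp, with the slide as a fixed block, with only the groups compared and with a replicate block but no slide block, and 1, 0 and 0 without replicate 1, 2 or 3. It was 1 with the filter on all 18 arrays, 2 with the replicate as a block, 11 without the dim array, 8 without 0.5 Gy 250-500 µm replicate 3 and 0 without 0.5 Gy 750-1000 µm replicate 2 or replicate 3, while it was 2 without replicate 1 of that strip. The 619 of the 16-array fit became 75, 2 and 6 without replicate 1, 2 or 3.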

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

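Of the tests below, those on the 16-array fit and on array position, basal keratinocytes and equal RNA were chosen after the results they weigh were seen.

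In 16 genes, each by its brightest probe, the dose effect at 250-500 µm differed from that at 750-1000 µm. They passed the threshold of limma's test of that difference in the 16-array fit, and in all 16 the effect was lower near the line. The 3 probes with a higher dose effect near the line do not stand for any of these genes. The difference was -2.05 for MX1, -1.59 for MMP1, -1.36 for CEACAM6, -1.21 for IFI27, -1.20 for SPINK6, a protease inhibitor of the skin, and -1.17 for both KRT19 and ALDH1A3, which makes retinoic acid. It was -1.14 for ANXA3, -1.10 for MMP9, -1.09 for FCRLB, -1.02 for LGALS1, a lectin, -0.98 for ANXA1, -0.91 for the protocadherin PCDHGA7, -0.89 for LAMA3, and -0.63 for both IL1B and PLAU. In 14 of the 16 the gene fell at 250-500 and 500-750 µm and changed less at 750-1000 µm, while FCRLB and PCDHGA7 rose at 750-1000 µm by 0.67 and 0.72. With all 18 arrays the adjusted p of these differences was 0.83 or 0.962, and PCDHGA7 turned to 0.16.

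The first pattern weighed is the dose difference averaged over the distances. With the replicate as a block the 5 probes passed with and without the poor arrays. Without that block 3 of the 5 passed when the poor arrays were left out, and for these 3 the poor arrays are excluded as the whole cause. For DMBT1 and FST the test cannot decide, because their calls without the poor arrays depended on the block. With no block their adjusted p in limma became 0.109 and 0.136 as their standard errors grew, from 2.61 ± 0.32 to 2.64 ± 0.48 and from -2.20 ± 0.29 to -2.01 ± 0.39. Chance differences between slides or tissues enter limma's p-values through the slide block, with 3 slides per dose. That block uses 1 slide correlation for all probes, 0.26 in the 16-array fit. Arrays of a slide are not independent, so standard errors and p-values of that fit may be too small. With the arrays of a slide averaged, 0 probes passed in the fit to 18 arrays. The splits of the 6 slides that also part each pair gave at most 8 probes against 1471 in the 16-array fit. There were 4 such splits, too few for a share under 0.05. With all 18 arrays each comparison had 10 splits, too few for a share under 0.05: 5 probes against at most 0 for the averaged dose, 5 against 0 at 250-500 µm, 1 against 0 at each of the other distances, and 787 against 0 in 4 splits for the 16-array fit at 750-1000 µm. The dose itself, the difference that the design names, stays open as a biological explanation.

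The second pattern is the difference between near and far strips of 0.5 Gy tissue. Array position on the slide follows distance in 0 Gy tissue too, yet there the 619 probes had a median difference of -0.057 in the direction seen at 0.5 Gy (quartiles -0.134 and 0.012), against 0.661 at 0.5 Gy. In experiments 1 and 3 the far arrays of 0.5 Gy tissue also had lower signal than the near ones, which was not tested as a cause. Fewer basal keratinocytes in the near strips could not be excluded: the basal list had a median of -0.215 (median absolute deviation 0.16) against -0.707 for the 416 lower probes, and KRT5 and KRT14, its abundant keratins, had 0.14 and -0.20, but members that go both ways decide nothing. For all 18 arrays 3 probes stood against at most 1 in the other splits in 0.5 Gy tissue, and in 0 Gy tissue the real split, with 8 probes at an unadjusted p under 0.05, was exceeded or met by others up to 170, with 10 splits each, too few for a share under 0.05. For the difference of dose effects, distances were permuted within slides, with the real order counted among the 100. In the 16-array fit the real order gave 21 probes and no other reached that, but the closest came to 20. That fit was chosen after seeing the data, so chance is not excluded. With all 18 arrays 47 of 100 gave as many (278 at an unadjusted p under 0.05, up to 1559 in the others). For the interaction it was 46 of 100 (168, up to 670). Why other orders reached such counts was not tested.

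The third pattern is how close the arrays of a 0 Gy slide lie. Their differences had a standard deviation from 0.108 to 0.167 over 12793 probes, which is 0.62 (median of 7 array pairs) of what repeated spots within an array give. Between experiments it was 0.394 to 0.605 in 0 Gy tissue. The same RNA on each array of a slide cannot be told apart from equal tissue there, because a spread between single arrays set against technical noise decides nothing. The near and far strips of 0.5 Gy slides differed at 619 probes in the 16-array fit, against 0 in 0 Gy tissue. This argues against the same RNA there but does not exclude it, because the far arrays were also dimmer. Their 75th percentile was 110 against 159.9 near the line in experiment 1, and 309.3 against 417.8 in experiment 3. In 0 Gy tissue it was 187.6 against 189.9 and 341 against 349.3. For the near and middle strips of 0.5 Gy slides the same RNA stays open, with 0 probes past the threshold (0 in 0 Gy tissue) and a spread of 0.69 and 0.59 times that of repeated spots. For the closeness of these arrays no biological explanation was tested.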

How the results depend on the processing

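Alternatives with a floor of 0.1, array weights or without poor arrays, and all on the 16-array fit, were chosen after seeing the data. The counts are of probes past the threshold, in this order: averaged dose (5 in the fit reported), 250-500 µm (5), 500-750 µm (1), 750-1000 µm (1), interaction (0), near minus far dose effect (0), and near against far at 0.5 Gy (3). Counts not given for an alternative stayed within 1.5 times the reported one. The count for near against far at 0 Gy was 0 in limma under every alternative, with 8 probes at an unadjusted p under 0.05 in the fit reported. Where no cause is given below, the cause was not tested.

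Quantile normalization gave 3 at 250-500 and 2 at 500-750 µm. Normexp gave 2 at 250-500 µm, 3 at 500-750 µm and 0 for near against far, and with quantile normalization 8 for the averaged dose and 0 at 500-750 and at 750-1000 µm. Without a filter the averaged dose had 26, 250-500 µm 13, 500-750 µm 12 and near against far 5. With the filter on all 18 arrays, which the dim array reduces to 6404 probes, the averaged dose, 250-500 µm and near against far had 1 each, the other distances 0, and 5 lists passed in place of 8. An intensity trend with robust variances gave 3 at 250-500 µm, and the floor of 0.1 gave 9 at 500-750 µm. Only the groups compared gave 0 at 250-500 µm, 500-750 µm and near against far, a fit with fewer samples. Without a slide block the averaged dose had 27, with slide means 0 (6 samples), and the slide as a fixed block gave 0 for near against far. An estimated correlation left 3 of the 8 lists.

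The replicate number as a block, which pairs the samples, gave 33 for the averaged dose and 2 at 500-750 µm, and without the slide block 39 and 2, with 0 for near against far. Leaving out replicates, in the fit to 18 arrays, its single-array versions and the 16-array fit, gave from 1 to 1924 for the averaged dose, 0 to 39 at 250-500 µm, 0 to 168 at 500-750 µm, 0 to 23 at 750-1000 µm, 0 to 3 for the interaction, 0 to 4 for near minus far, 0 to 75 for near against far at 0.5 Gy and 5 to 12 lists. A fit that leaves 1 array in a group assumes that it varies like the other groups.

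Array weights, which were 0.0243 and 0.0796 for the poor arrays, gave 79, 68, 80, 15, 85, 71 and 730 in the order above. Without the dim array the counts were 19, 12, 16 at 500-750 µm, 1 for the interaction, 1 for near minus far and 11 for near against far, and without the scattered array 8 at 250-500 µm. Without both they were 14, 24, 24, 3, 35, 32 and 397. The 16-array fit gave 1471, 328, 278, 787, 25, 21 and 619, with quantile normalization 1121, 342, 299, 738, 30, 39 and 628, and with normexp 1808, 341, 563, 4978, 2551, 963 and 2863. With its filter on all 16 arrays it gave 1565, 426, 373, 1168, 402, 170 and 1025, and without the slide block 3814, 426, 350, 1114, 8, 8 and 95.

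The mean correlation of dose effects between distances was 0.205. It was 0.31 with normexp, 0.125 without a filter, 0.166 with the filter on all 18 arrays, 0.408 with array weights, 0.25 without the dim array, 0.243 without the scattered one, 0.335 without both, 0.331 in the 16-array fit, 0.232 with the floor of 0.1 and from 0.19 to 0.224 when a replicate was left out. Between 250-500 and 500-750 µm (0.168) it was 0.566 with array weights, 0.375 without the dim array, 0.543 without both poor arrays, 0.564 in the 16-array fit and 0.08 to 0.274 by replicate. Between 250-500 and 750-1000 µm (0.303) it was 0.651 with normexp, 0.163 without a filter, 0.441 with the filter on all 18 arrays, 0.414 with array weights, 0.229 without the dim array, 0.229 without both, 0.235 in the 16-array fit, 0.389 with the floor of 0.1 and 0.254 to 0.334 by replicate. Between 500-750 and 750-1000 µm (0.145) it was -0.09 with the filter on all 18 arrays, 0.244 with array weights, 0.256 without the scattered array, 0.232 without both and 0.092 to 0.236 by replicate.

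The NF-kB list turned to higher for the averaged dose with the filter on all 18 arrays (adjusted p 0.000481). With normexp in the 16-array fit, cholesterol synthesis, melanocyte, NRF2 and oxidative phosphorylation lists turned for near minus far (adjusted p 0.0012, 0.625, 0.00336 and 3.35e-05) and for near against far (0.00414, 0.7, 0.00187 and 7.61e-05). For near against far the NRF2 list also turned with quantile normalization (0.0369), no slide block (0.0464) and without replicate 1, with 0.0395 to 0.397 when a replicate was left out. CDH4 at 250-500 µm had 0.09 with normexp, and KBTBD7 for near against far had 1.24 without the poor arrays, 1.2 in the 16-array fit and 1.34 with quantile normalization there.

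The fit reported called at most 5 probes in any comparison, so most named gene results were not calls there. Cases kept below are therefore mostly results not called under either setting, and say little of how stable the calls are. The series table, among the settings chosen in advance, holds the same values and could only keep a result. Over 200 results on named genes and 96 on lists, the settings chosen in advance kept direction and side of the threshold in 4963 and 1198 cases, lost a call in 146 and 42, gained one in 116 and 47 and changed sign with no call on either side in 88 and 132. Those added later did so in 1505 and 879, 36 and 27, 898 and 86, and 88 and 245 cases. Of 146 gene results named from the 16-array fit, 133 passed with quantile normalization, 125 with normexp (where 141 kept their sign) and 133 without the slide block, and 102, 53 and 3 without replicate 1, 2 or 3 (the last of 145). Signal over background limits what can be said of CFB, DMBT1, FST, BMP6, CDH4, LRRTM1, S100A7A, SLC13A5, BMP2, RALGPS1, G0S2 and HS3ST1. Each has a group with no array above it.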

Other observations

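The tests on transcription factor targets below were chosen after the averaged dose effects were seen.

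In 0.5 Gy tissue some genes that rose with dose were also higher near the line than far from it in the 16-array fit. SERPINA3 was higher at 250-500 than at 750-1000 µm by 0.80 ± 0.17 (adjusted p 0.0436), SOD2 by 0.51 ± 0.10 (adjusted p 0.0326), PGLYRP2 by 0.38 ± 0.08 (adjusted p 0.0467) and TNFAIP2, induced by tumour necrosis factor, by 0.37 ± 0.08 (adjusted p 0.0456). AKR1C1, which reduces steroids and prostaglandins, was higher near the line by 0.50 ± 0.10 (adjusted p 0.0342). SAA1 and CYP1B1 did not pass there, with 0.26 ± 0.09 (adjusted p 0.165) and 0.17 ± 0.18 (adjusted p 0.645). Lower near the line were TYROBP, an adaptor of myeloid receptors (-0.82 ± 0.19, adjusted p 0.0483), DSC2, a desmosomal cadherin (-0.58 ± 0.12, adjusted p 0.0415), and ZBED2 (-0.64 ± 0.10, adjusted p 0.0222). Adjusted p-values of the 16-array fit may be too small, and without its slide block the near against far calls fell from 619 to 95. In experiments 1 and 3 the far 0.5 Gy arrays were also dimmer than the near ones, which was not tested as a cause. Only the near minus far difference of dose effects tests whether the dose effect changed with distance, and none of these 10 genes passed it.

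CYP1B1 and CYP1A1 are textbook targets of the aryl hydrocarbon receptor. If the receptor was active, its other targets may have risen with them, but 0 of 5 measured targets passed the threshold upward in the 16-array fit. NQO1 had 0.61 ± 0.18 (adjusted p 0.0724), CYP1A2 0.40 ± 0.11 (adjusted p 0.0618), ALDH3A1 0.19 ± 0.12, UGT1A6 0.12 ± 0.06 and TIPARP -0.06 ± 0.08, and AHRR was not measured. The rise of other aryl hydrocarbon receptor targets was thus not found, though NQO1 and CYP1A2 lie close to the threshold.

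Higher SAA1, SAA2, SERPINA3 and metallothionein genes with lower MMP1, MMP9 and MMP10, single genes picked from the top of the 16-array fit beside a list, could come from a glucocorticoid response. Of 8 measured glucocorticoid targets 0 rose, CEBPD fell by 0.19 ± 0.04, and the median was -0.12, with FKBP5 at -0.15 ± 0.10 and TSC22D3 at 0.63 ± 0.33. For SAA1, SAA2 and SERPINA3 a STAT3 response was also tested: 0 of 5 measured STAT3 targets rose, with a median of -0.07, and SOCS3 was not measured. Neither response was found in these genes.

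The scattered array differed from the mean of its slide neighbours with a standard deviation of 1.326, against 0.13 between the neighbours. The bases at each position of its 60-base probes explained 21.6% of the variance of that difference, in probes held out of the fit, and -0.7% between the neighbours.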
